A study of Homo sapiens with 15 samples.

How the data were processed

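The data are poly-A RNA libraries from whole cells or from isolated focal adhesions of 2 human primary cell types. These were umbilical vein endothelial cells (HUVEC) and dermal fibroblasts (HDF). Per the labels' protocols, the cells were seeded on fibronectin. Focal adhesions were exposed on the dish by 3 min in a low ionic strength buffer with 2.5 mM triethanolamine, after which a jet of saline removed the cell bodies. RNA was extracted with Trizol, and 500 ng of total RNA per library went into the Lexogen QuantSeq forward kit, which reads the 3′ ends of polyadenylated transcripts, with 13 to 14 PCR cycles.

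The deposited table holds expected counts per gene, which the authors had not normalized and which need not be whole numbers. Of the non-zero values, 63.7% lay within 0.001 of a whole number, so reads had been divided among genes in the table as deposited. STAR, DESeq and the genome build GRCh38 are named in the submitters' processing notes, without versions. The counting program, its use of strand and the annotation release are not given in the sources used here. Expected counts were rounded to whole numbers before any test. The table lists 61630 genes by Ensembl identifier and a row of totals, which was left out of library sizes and tests. The sum over genes was 1.032 to 1.037 times that total in each library. Columns of gene length and of pooled group values were not used. Of the identifiers, 99.9% matched the table of gene names, and 19915 genes, 1776 of them tested, had no symbol. Gene coordinates, transcript lengths and GC content came from GENCODE release 29 on GRCh38, a release older than the file's own identifiers.

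Groups and replicate numbers were taken from the sample titles. In 3 of the 15 libraries the characteristics name another preparation or another cell type than the title. These are HDF focal adhesion replicate 1, HUVEC whole cell replicate 1 and HUVEC focal adhesion replicate 1. The titles were kept for all libraries, and the alternatives include a fit without these 3 libraries and a fit with the groups given by the characteristics. Nothing in the labels says that replicates came from separate donors or cultures, so p-values measure only the spread between these libraries, which may be technical. Counts summed over genes ranged from 12114897 to 18995151 per library. Counting intervals and floors cover counting error only, since the reads carry no molecular identifiers.

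Genes were kept by the default expression filter of edgeR 4.0.16, which left 16448. Libraries were scaled by TMM, all 4 groups entered 1 quasi-likelihood fit with 11 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 5 contrasts were focal adhesions against whole cell in HUVEC, the same in HDF, the difference between these effects, and HUVEC against HDF in whole cells and in focal adhesions. Levels are given as CPM, the count over the library size after TMM scaling. In a simulation on the 16448 genes, the HUVEC contrast recovered 18.6% of genes changed 2-fold and 67.1% of those changed 4-fold. The HDF contrast recovered 21.4% and 64.3%, and the difference of effects 4.29% and 45.7%.

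Fixed gene lists, 24 in number, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. They held mitochondrially encoded mRNAs, cytosolic ribosomal proteins, translation factors and other TOP mRNAs, nuclear-encoded respiratory chain subunits, extracellular matrix, endoplasmic reticulum (ER) translocation and folding machinery, focal adhesion proteins, the actin and contractile cytoskeleton, and the tubulin and vimentin cytoskeleton. Others held protrusion-localized mRNAs, nuclear long noncoding RNAs, snoRNA host transcripts, stress granule proteins, very long mRNAs, immediate early genes, heat shock genes, inflammatory and interferon genes, and cell cycle genes. Markers of endothelial cells, fibroblasts, smooth muscle and pericytes, epithelium and keratinocytes, immune cells and erythroid cells completed the set. KANK2 and PALLD stood in both the protrusion and the focal adhesion list. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it.

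Shares of counts per gene class were compared by exact two-sided permutation tests over 12 comparisons. Spearman correlations related fold changes to transcript properties across genes, as description only. Properties came from protein-coding transcripts matched by identifier, so genes without such a transcript had no value. Of the tested genes, 76.9% had one. Properties are given mainly for genes with a mean of at least 10 CPM, of which 92.7% had a value.

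The groups, tests, gene lists, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took, per comparison, genes past the threshold with at least 10 CPM and no overlap between the groups' libraries. From these it took the 10 largest increases and the 10 largest decreases, besides called members among each list's 4 most changed, and 8 genes of the study's subject. Genes on the Y chromosome, XIST and TSIX were left out. The alternative settings fixed then were DESeq2 size factors, library totals without a composition factor, DESeq2 1.42.0, limma-voom with sample weights, no expression filter, a filter of 5 CPM, only the compared groups in the fit, the replicate number as a block, each library left out in turn, thinning to the smallest library, and a minimum log2 fold change of 1. Coding length, the restriction to 10 CPM for transcript properties, the leave-one-out values of properties and shares, and list tests without HDF whole cell replicate 1 were chosen after seeing the data. Analyses ran in R 4.3.3 and Python 3.11.15, with plots in matplotlib 3.10.9.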

Results

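Polyadenylated RNA was sequenced from whole cells and from isolated focal adhesions, the protein complexes that anchor a cell's actin cytoskeleton to the matrix beneath it. HUVEC, endothelial cells of the umbilical vein, gave 4 whole cell and 4 focal adhesion libraries. HDF, dermal fibroblasts, gave 3 whole cell and 4 focal adhesion libraries. The series concerns ribonucleoprotein complexes with G3BP1, an RNA-binding protein of stress granules, and the movement of focal adhesion proteins and cells.

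The counts summed over genes were 15197887, 16653983, 14883064 and 14451449 in HUVEC whole cell replicates 1 to 4, and 18927089, 15373125, 18096211 and 18995151 in HUVEC focal adhesion replicates 1 to 4. HDF whole cell replicates 1 to 3 had 12894150, 15387760 and 14117554 counts, and HDF focal adhesion replicates 1 to 4 had 16197479, 12227436, 12114897 and 14770711. The first principal component of log2 CPM held 65.4% of the variance and separated HUVEC from HDF, with all 15 libraries on the side of the cell type in their title. HDF whole cell replicate 1 stood apart on the second component, which held 7.89% of the variance. Its correlation to the other libraries of its group was 0.917, against 0.94 to 0.976 in the other libraries. Of 8444 genes with at least 10 CPM, 99 were over 10-fold lower in it than the mean log2 CPM of replicates 2 and 3. Over 10-fold higher were 0 genes, and 0 differed so between replicates 2 and 3. TMSB4X, which binds actin monomers, was at 6.47 CPM there and at a mean of 662 CPM in the other replicates. PFN1, another binder of actin monomers, was at 14.2 against 681 CPM, and EEF1A1, a translation elongation factor, at 141 against 1890 CPM. HDF values are therefore also given without this library where a count or a list rests on it.

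The first comparison asked which mRNAs were enriched at focal adhesions of endothelial cells. Among the genes with large increases were AHNAK, UACA, the cytoskeletal linkers PLEC, MACF1 and DST, and RAB13. AHNAK (ENSG00000124942, GRCh38 chromosome 11, 62433542 to 62556235), a giant scaffold protein at the membrane, was 7.84-fold higher in focal adhesions. RAB13 (ENSG00000143545, chromosome 1, 153981617 to 153986358), a small GTPase of vesicle traffic whose mRNA is a standard example of localization to protrusions, was 5.48-fold higher. G3BP1 mRNA itself did not pass the test in HUVEC.

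By level, AHNAK was at 3180 ± 225 CPM (SD, n = 4) in focal adhesions and 406 ± 47.5 CPM (SD, n = 4) in whole cells, a log2 fold change of 2.97 ± 0.205 (SE; adjusted p = 1.32e-07). UACA (ENSG00000137831, chromosome 15, 70654554 to 70763593) was at 688 ± 213 against 116 ± 39.2 CPM (2.57 ± 0.298, adjusted p = 5.85e-05). RAB13 was at 872 ± 78.1 against 159 ± 4.97 CPM (2.45 ± 0.201, adjusted p = 6.26e-07), and a gene on its strand overlaps it. Log2 fold changes were 2.48 in ZSWIM9 and 2.41 in CACNG8, a subunit of a membrane channel family, whose locus also overlaps a gene on its strand. ERG, a transcription factor of endothelial identity, rose 3.22-fold, from 89.5 ± 9.84 to 288 ± 27.1 CPM (adjusted p = 5.88e-07).

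Of 11 protrusion-localized mRNAs, 6 rose in HUVEC focal adhesions and 0 fell, with 9 higher when adjusted over the list alone. The 6 were RAB13, NET1, KANK2, TRAK2, DDR2 and KIF1C. NET1, a guanine nucleotide exchange factor, rose 5.09-fold, and TRAK2, an adaptor of mitochondrial transport, 5.3-fold. KANK2, a talin-binding protein at the rim of adhesions, rose 4.53-fold, from 17.8 ± 0.888 to 80.4 ± 17.6 CPM. The collagen receptor DDR2 had a log2 fold change of 1.95 and the kinesin KIF1C of 1.68. INPP1 at -0.11, DYNLL2 at 0.03, CYB5R3 at 0.39 and PKP4 at 0.52 did not pass. The list's median log2 fold change was 1.68 (camera, adjusted p = 9.78e-24 with the preset and 5.63e-05 with an estimated correlation).

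Among 63 mRNAs of focal adhesion proteins, 6 rose and 0 fell, with 8 higher when adjusted over the list alone. Among them were KANK2, KANK1 (3.95-fold), FLNA (2.63-fold), TLN2 and TNS1, and the other 57 did not pass. FLNA, the major actin crosslinker of adhesions, was at 2510 ± 360 against 952 ± 56.2 CPM. The mRNAs of the core adhesion proteins vinculin (VCL, log2 fold change -0.16), paxillin (PXN, -0.24), talin 1 (TLN1, 0.45) and zyxin (ZYX, 0.21) did not pass. Beta-actin mRNA, ACTB, was at 2760 ± 352 against 2680 ± 463 CPM, and its difference did not pass (log2 fold change 0.04, negative under scaling by library totals and without some libraries). The list median was 0.14 (adjusted p = 1.58e-05 with the preset and 0.00117 with an estimated correlation).

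Very long mRNAs also rose as a group, with 6 of 25 higher and 0 lower, and 7 higher when adjusted over the list alone. These were AHNAK, PLEC, MACF1, DST, SPTBN1 and SPTAN1, which besides AHNAK encode cytoskeletal linkers and spectrins. PLEC rose 5.89-fold and MACF1 5.68-fold, and the list median was 0.29 (adjusted p = 1.41e-12 and, with an estimated correlation, 0.0465). Mitochondrially encoded mRNAs had a median of 0.47, with 1 of 13 higher and 8 when adjusted over the list alone (adjusted p = 9.2e-12 and, with an estimated correlation, 0.0465). The cytochrome oxidase subunit MT-CO1 rose 1.82-fold, from 1500 ± 229 to 2720 ± 170 CPM. Of the ER translocation and folding machinery, 31 of 35 members had a positive sign, with 1 higher and 8 when adjusted over the list alone (median 0.38, adjusted p = 1.15e-09 and 0.0247 with an estimated correlation). SEC62, a subunit of the ER translocation machinery, rose 2.12-fold.

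A further 6 lists passed the preset test in HUVEC and not with an estimated correlation. Of these, fry passed snoRNA host transcripts (fry adjusted p = 0.0394), endothelial markers (0.0185) and smooth muscle markers (0.000414), and not the others. Ribosomal proteins (median -0.09, adjusted p = 0.00276 and 0.517 with an estimated correlation), respiratory chain subunits (-0.13, 0.00816 and 0.518), nuclear long noncoding RNAs (-1.19, 0.00138 and 0.296) and snoRNA host transcripts (-0.26, 0.000437 and 0.0648) were lower. Endothelial markers (0.18, adjusted p = 0.000437 and 0.236 with an estimated correlation) and smooth muscle markers (1.10, 0.0295 and 0.0943) were higher, each with 1 gene called, ERG and SMTN. Of the lower lists 0 members passed over all genes, and when adjusted over the list alone 3 nuclear long noncoding RNAs and 1 snoRNA host transcript did. The nuclear RNA MALAT1 was at 473 ± 172 against 1150 ± 809 CPM and did not pass (log2 fold change -1.29, adjusted p = 0.486). MIRLET7A1HG, a microRNA host transcript, fell by 1.40 on the log2 scale.

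The remaining lists did not pass in HUVEC. Medians and adjusted p were 0.05 (0.129) for TOP mRNAs, -0.02 (0.388) for extracellular matrix, 0.07 (0.272) for actin and contractile genes, -0.01 (0.219) for tubulin and vimentin genes, and -0.01 (0.644) for stress granule proteins. They were -0.12 (0.159) for immediate early genes, 0.10 (0.397) for heat shock, 0.13 (0.645) for inflammatory and interferon genes, and 0.05 (0.155) for the cell cycle. Markers of fibroblasts had 0.09 (0.819), of epithelium 0.04 (0.697) and of immune cells 0.21 (0.388). The tubulin, stress granule and extracellular matrix medians and means differed in sign, and the fibroblast test pointed down beside a positive median. The tubulin list held 1 higher gene, MAP1B. When adjusted over the list alone, 2 tubulin genes, 1 actin gene, 1 inflammatory gene and 1 cell cycle gene were higher. With scaling by library totals the TOP, actin, cell cycle and epithelial medians were negative. No erythroid marker could be tested in any comparison, since 0 of 8 passed the expression filter.

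In the test across all genes, 130 of 16448 passed in HUVEC (edgeR quasi-likelihood, Benjamini-Hochberg), 127 higher and 3 lower in focal adhesions. At an absolute log2 fold change of at least 1 these were 86 and 3. The 3 lower genes, of which only MIRLET7A1HG is in the rule for named genes and the others are named after their values were seen, were MIRLET7A1HG, RNVU1-25 (log2 fold change -1.44) and a gene without a symbol (ENSG00000269578, -2.08). Leaving out HUVEC focal adhesion replicate 4 left 78 genes. The call of DST ended without HUVEC whole cell replicate 1, 2 or 4 or focal adhesion replicate 1, 3 or 4, and that of MIRLET7A1HG without any of the libraries except whole cell replicate 1 (adjusted p from 0.0546 to 0.187).

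G3BP1 (ENSG00000145907, chromosome 5, 151771045 to 151812785) was at 370 ± 13.2 CPM in HUVEC focal adhesions and 296 ± 17.3 CPM in whole cells (log2 fold change 0.32 ± 0.129, adjusted p = 0.448). Its paralog G3BP2 had a log2 fold change of 0.31 (adjusted p = 0.722).

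**Figure D1:**
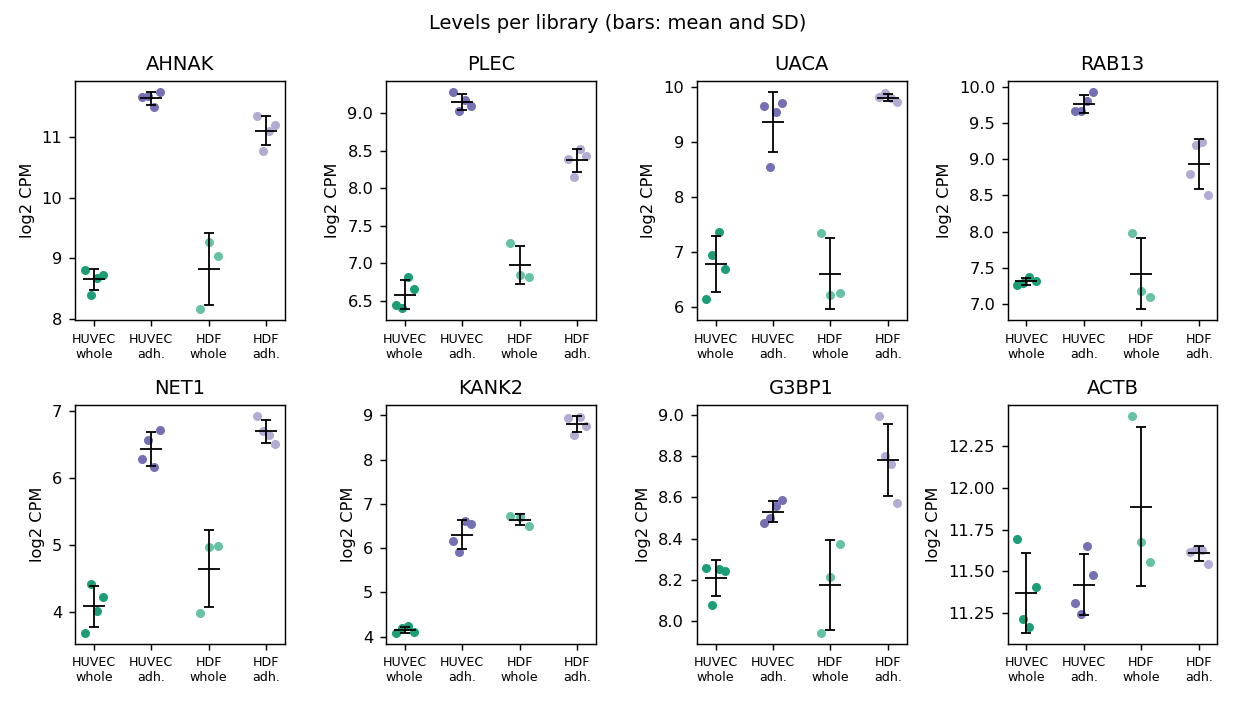
Expression of 8 genes in each library, as log2 CPM, by cell type and preparation, with each group's mean and SD as bars. In both cell types AHNAK, PLEC, UACA, RAB13, NET1 and KANK2 were higher in focal adhesions, while G3BP1 differed less and ACTB did not pass the test in either.

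The second comparison put the same question to fibroblasts. Among called genes with at least 10 CPM and no overlap between the groups' libraries, the largest increases were in UACA and BAZ1A. UACA was 8.55-fold higher in HDF focal adhesions, at 893 ± 40 CPM (SD, n = 4) against 104 ± 50.5 CPM (SD, n = 3). BAZ1A (ENSG00000198604, chromosome 14, 34752731 to 34875647), a subunit of chromatin remodeling complexes, was 5.94-fold higher. IQGAP1, a scaffold at the leading edge, and FLNA were also among the genes with higher levels, as was G3BP1 by 1.52-fold. Ribosomal protein mRNAs were lower as a list, though not with an estimated correlation.

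By test, UACA had a log2 fold change of 3.10 ± 0.343 (SE; adjusted p = 6.8e-05), and BAZ1A, at 319 ± 42.8 against 53.8 ± 15.1 CPM, of 2.57 ± 0.279 (adjusted p = 5.67e-05). AHNAK rose 4.64-fold, from 478 ± 172 to 2220 ± 355 CPM (adjusted p = 2.64e-05). IQGAP1 rose from 179 ± 52.1 to 727 ± 66.1 CPM (log2 fold change 2.02 ± 0.206, adjusted p = 3.1e-05). Other named increases on the log2 scale were CENPF, a kinetochore protein, at 2.42 (3.30 without HDF whole cell replicate 1, where its level was highest of the whole cell libraries), ZSWIM9 at 2.23, and PPP4R3B, a regulatory subunit of protein phosphatase 4, at 1.95.

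Of the 11 protrusion-localized mRNAs, 7 rose in HDF and 0 fell, with 9 higher and 1 lower when adjusted over the list alone. KANK2 (ENSG00000197256, chromosome 19, 11164267 to 11197791) rose 4.5-fold, from 99.9 ± 8.55 to 450 ± 57.4 CPM (adjusted p = 5.6e-06). NET1 rose from 26.1 ± 9.09 to 104 ± 12.9 CPM, RAB13 from 178 ± 64.7 to 499 ± 115 CPM and TRAK2 from 62.7 ± 1.92 to 166 ± 19.6 CPM. DDR2, KIF1C and PALLD, the actin-binding protein palladin, were the other genes that rose. INPP1 at -0.38, DYNLL2 at -0.61, CYB5R3 at 0.40 and PKP4 at 0.51 did not pass over all genes. The list median was 1.07 (adjusted p = 4.46e-13 and, with an estimated correlation, 0.000542), and 1.32 with 8 higher without HDF whole cell replicate 1.

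Among the 63 focal adhesion proteins, 10 rose and 0 fell, with 15 higher when adjusted over the list alone. FLNA rose from 1510 ± 461 to 5410 ± 852 CPM, and TLN1, which links integrins to actin, from 315 ± 37.7 to 745 ± 42.6 CPM (log2 fold change 1.24 ± 0.177, adjusted p = 0.000846). Others were KANK1, KANK2, TLN2, TNS1, PALLD, NEXN, an actin filament protein at 1.35, and ACTN1, an actin crosslinker at 0.71. VCL (0.16), PXN (0.05, and -0.39 without HDF whole cell replicate 1 and negative too without focal adhesion replicate 4), ZYX (0.63) and ACTB (-0.33) did not pass. The list median was 0.16 (adjusted p = 1.06e-08 and, with an estimated correlation, 0.00023).

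Very long mRNAs had 6 of 25 higher in HDF, namely AHNAK, SPTBN1, SPTAN1, MACF1, PLEC and UTRN, and 8 when adjusted over the list alone (median 0.47, adjusted p = 2.4e-12 and 0.0551 with an estimated correlation). Of stress granule proteins 1 of 37, G3BP1, rose, and 3 when adjusted over the list alone (median 0.26, adjusted p = 1.08e-05 and 0.0777 with an estimated correlation). G3BP1 was at 442 ± 53.2 against 292 ± 43 CPM (log2 fold change 0.60 ± 0.141, adjusted p = 0.0453). This call ended without HDF whole cell replicate 2 or any 1 of the focal adhesion replicates, where adjusted p ran from 0.0502 to 0.128. G3BP2, at 0.79 ± 0.192, did not pass (adjusted p = 0.0543), and passed without HDF focal adhesion replicate 2 (adjusted p = 0.0436). For the ER machinery the median was 0.24 with 1 gene higher, SEC62 (log2 fold change 1.07; list adjusted p = 1.08e-05 and 0.0782 with an estimated correlation), and 2 when adjusted over the list alone. This median was 0.12, with 3 genes higher, without HDF whole cell replicate 1.

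Cytosolic ribosomal protein mRNAs had a median of -0.34 in HDF, with 3 of 78 lower and 0 higher, and 29 lower when adjusted over the list alone. The 3 were RPS20 (-0.59), RPL12 (-0.67) and RPS27 (-0.65), and the list had an adjusted p of 2.13e-10 with the preset (adjusted p = 0.215 with an estimated correlation). Reads of these genes can also match near-identical copies. Without HDF whole cell replicate 1, 17 were lower, with a median of -0.44 (adjusted p = 0.2 with an estimated correlation). Respiratory chain subunits had a median of -0.20, with 0 of 72 past the test over all genes and 12 lower when adjusted over the list alone (adjusted p = 0.000245 and 0.324 with an estimated correlation); without that library 9 were lower, with a median of -0.37. Among random lists matched on coding length and level, whose own median was -0.20, the respiratory median lay at percentile 47.72. Among snoRNA host transcripts 1 of 14, SNHG16 (-0.60), was lower (median -0.43, adjusted p = 0.00116 and 0.0953 with an estimated correlation), and 4 without that library. The named single genes that fell were of moderate or low level. VEGFB, a vascular growth factor, went from 25 ± 1.63 to 12.1 ± 3.12 CPM (log2 fold change -1.05, adjusted p = 0.0181), and the antisense transcript VPS9D1-AS1 had -1.11. Others were IRAK1, a kinase of interleukin and Toll-like receptor signaling, at -0.95, ULK1, a kinase that starts autophagy, at -0.95, LAMTOR4, part of the lysosomal Ragulator complex, at -0.95, and TIMM10B, a mitochondrial import protein, at -0.94. RRP7BP stood at -1.40, MAPKAPK5-AS1 at -1.12, PDRG1 at -1.06 and MTX1, a mitochondrial outer membrane protein, at -1.04. These were -0.65 in MTX1, -0.60 in LAMTOR4 and -0.59 in IRAK1 without HDF whole cell replicate 1.

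Further lists past the preset test in HDF had no call with an estimated correlation. Heat shock genes had a median of 0.22 (adjusted p = 0.00641 and 0.0551 with an estimated correlation), mitochondrially encoded mRNAs 0.20 (0.0147 and 0.324; 0.38 without HDF whole cell replicate 1) and extracellular matrix 0.15 (0.014 and 0.295). Actin and contractile genes had a median of -0.01, a mean of 0.05 and a test that pointed up (adjusted p = 0.0387 and 0.215 with an estimated correlation), with CALD1 higher at 1.57 (2.18 without HDF whole cell replicate 1); the median was 0.01 with DESeq2 size factors. Without HDF whole cell replicate 1 the heat shock (adjusted p = 0.106), extracellular matrix (0.302) and actin lists (0.915) no longer passed, and the cell cycle list did with the preset alone (0.0105, and 0.227 with an estimated correlation). The heat shock median was then 0.083, with 3 genes higher and 1 lower, and the extracellular matrix median was 0.084. Lists that did not pass had medians of 0.10 (adjusted p = 0.824) for TOP mRNAs, beside a negative mean, 0.15 (0.0797) for tubulin and vimentin genes with MAP1B higher, -0.34 (0.284) for nuclear long noncoding RNAs, and 0.10 (0.18) for immediate early genes. For inflammatory genes the median was 0.15 (0.125), and for the cell cycle, with CENPF higher, it was -0.004 beside a mean of 0.16 (0.0674) and was positive under the other scalings. Markers of endothelium had 0.39 (0.125), of fibroblasts 0.11 (0.125), of smooth muscle, with SMTN higher, 0.05 (0.21), of epithelium 0.22 (0.25) and of immune cells 0.74 (0.207). PECAM1, the endothelial marker that passed in HDF, was at 0.657 ± 0.213 against 0.104 ± 0.127 CPM, near the floor; its log2 fold change was 2.43, and 3.88 without HDF whole cell replicate 2. When adjusted over the list alone, 3 tubulin genes were higher and 2 lower, 3 cell cycle genes higher and 1 lower, and 2 inflammatory genes higher. MALAT1 had a log2 fold change of -0.32 that did not pass, and 0.59 without HDF whole cell replicate 1. Medians also changed sign without that library for nuclear long noncoding RNAs (0.17), immediate early genes (-0.02), TOP mRNAs (-0.12) and tubulin and vimentin genes (-0.04), none of which passed, and for the cell cycle (0.18).

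In the test across all genes, 198 passed in HDF (edgeR quasi-likelihood, Benjamini-Hochberg), 143 higher and 55 lower, and 99 and 20 of these had an absolute log2 fold change of at least 1. The counts were 388 higher and 210 lower without HDF whole cell replicate 1. With the HDF groups alone fitted, edgeR called 62 higher and 0 lower (1584 in both directions at an unadjusted p under 0.05), and DESeq2 on all groups called 421 higher and 308 lower. Without the libraries with contradicting labels, 89 were higher and 6 lower. Leaving out whole cell replicate 2 left 67 higher and 28 lower, and whole cell replicate 3 left 100 and 92. Focal adhesion replicate 1 left 80 and 12 when omitted, replicate 2 left 120 and 79, replicate 3 left 94 and 25, and replicate 4 left 95 and 19. Of 34 named genes called in HDF, 20 kept their call without any 1 library. The other 14 lost it in at least 1 case, with adjusted p from 0.0502 to 0.128. They were CALD1, CENPF, G3BP1, IRAK1, LAMTOR4, MAP1B, MAPKAPK5-AS1, MTX1, PDRG1, PECAM1, RRP7BP, TIMM10B, ULK1 and UTRN. By library, 12 were lost without focal adhesion replicate 1, 3 without replicate 2, and 8 each without replicates 3 and 4. Without whole cell replicates 1, 2 and 3 the losses were 2, 9 and 5.

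**Figure D2:**
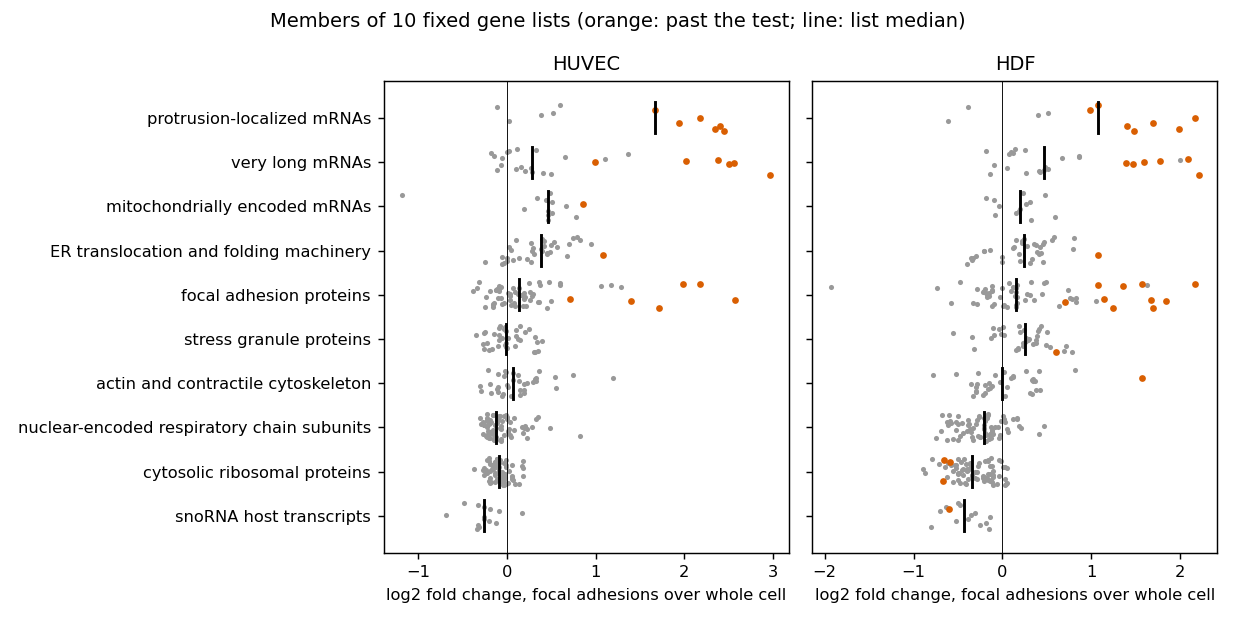
Log2 fold changes of focal adhesions over whole cells for the members of 10 gene lists, in HUVEC and HDF, with a point per gene, orange where it passed the test, and a line at each list's median. Protrusion-localized mRNAs had the highest medians, 1.68 in HUVEC and 1.07 in HDF.

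The next question was whether both cell types held the same mRNAs at focal adhesions. Of the genes higher in HUVEC and in HDF focal adhesions, 64 were shared, where 1.1 would be shared if calls were independent. The shared genes included AHNAK, UACA, PLEC, MACF1, RAB13, NET1, KANK2, TRAK2 and SEC62. Without HDF whole cell replicate 1, 80 were shared, against 3 if independent. Of the 127 genes higher in HUVEC, 124 had a positive log2 fold change in HDF, and of the 143 higher in HDF, 140 had one in HUVEC. A single gene, without a symbol (ENSG00000269578), was lower in both, and 0 genes were called in opposite directions.

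Across the 16448 genes, the log2 fold changes in HUVEC and HDF had a Pearson correlation of 0.223 and a Spearman correlation of 0.315, and 63.2% had the same sign. Among the 8444 genes with at least 10 CPM the correlations were 0.499 and 0.535. Genes are not independent replicates, and the comparisons shared no library. Without HDF whole cell replicate 1 the Pearson correlation was 0.138 over all genes and 0.428 among those with at least 10 CPM.

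The effect itself was then compared between cell types. At the smallest adjusted p, 0.139, PLEC had a log2 effect 1.17 ± 0.213 (SE) larger in HUVEC and did not pass. For BAZ1A the effect was lower in HUVEC by a log2 difference of -1.19 (adjusted p = 0.949), and for G3BP1, called in HDF alone, no difference between cell types passed. In edgeR 0 genes passed, with 797 at an unadjusted p under 0.05, while DESeq2 called 10 and limma-voom with sample weights 12. Without HDF whole cell replicate 1, and without HDF focal adhesion replicate 4, 1 gene passed.

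**Figure D3:**
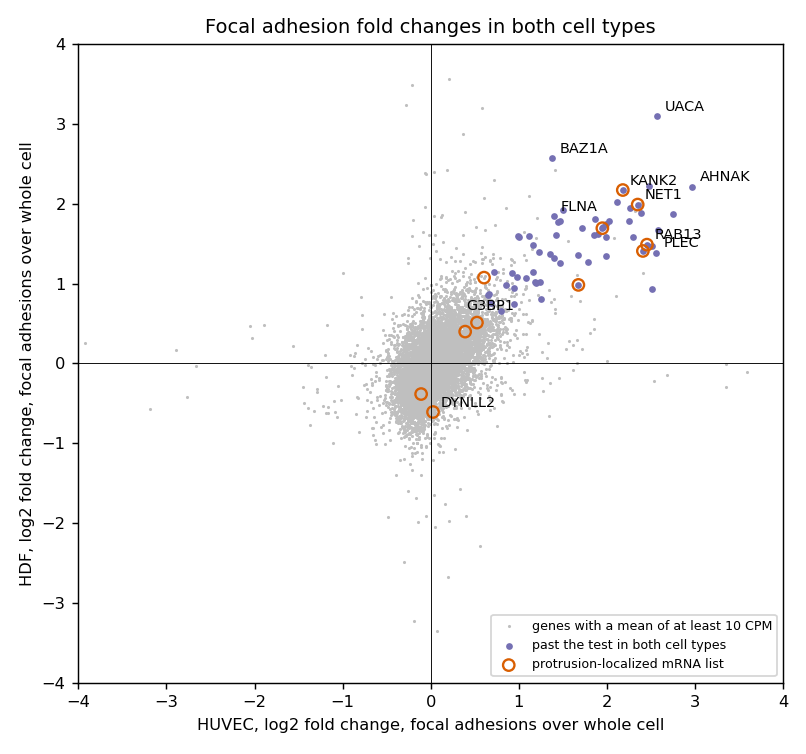
Log2 fold change of focal adhesions over whole cells in HUVEC (horizontal) and HDF (vertical) for genes with at least 10 CPM, in grey, with genes called in both in purple and protrusion-localized mRNAs circled in orange; 2 genes lie outside the axes. Genes called in both lay at the upper right, and the Pearson correlation of the genes shown was 0.499.

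Shares of all counts gave the same classes on another scale. Ribosomal protein mRNAs took 10.4 ± 0.539% (SD, n = 4) of counts in HDF focal adhesions and 13.1 ± 1.11% (SD, n = 3) in whole cells (exact permutation test, two-sided, p = 0.0286, the smallest it can give, adjusted p = 0.293 over 12 tests), where the whole cell mean was 13.8% without HDF whole cell replicate 1 (exact p = 0.0667, again the smallest possible). In HUVEC they took 13 ± 0.753% against 14.6 ± 1.43% (exact p = 0.114, adjusted 0.293). Mitochondrially encoded mRNAs took 6.48 ± 0.605% of counts in HUVEC focal adhesions and 5 ± 0.893% in whole cells (exact p = 0.0571, adjusted 0.293), and 5.25 ± 0.275% against 4.74 ± 0.703% in HDF (exact p = 0.229), or against 4.35% without HDF whole cell replicate 1 (exact p = 0.0667). Nuclear long noncoding RNAs took 0.0625% against 0.143% in HUVEC and 0.0642% against 0.0772% in HDF. The HUVEC whole cell values were spread from 0.0313% in replicate 1, below every focal adhesion library, to 0.249% in replicate 3, and the HDF whole cell mean was 0.0488% without replicate 1, which turns the sign of the difference. Endothelial markers took 0.463% against 0.413% of counts in HUVEC and 0.0206% against 0.0183% in HDF, and fibroblast markers 0.0184% against 0.0198% in HUVEC and 0.351% against 0.323% in HDF (0.347% without HDF whole cell replicate 1). The 10 most abundant genes took 8.93% against 8.5% in HUVEC and 7.93% against 8.24% in HDF, where the whole cell mean was 7.78% without replicate 1 and the sign turned as well. None of the 12 tests passed after adjustment.

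Enriched mRNAs tended to have long coding sequences. In the fifth of genes with the longest coding sequences, with a median of 3496.5 bases, 53 genes were called higher in HUVEC focal adhesions and 84 in HDF, against 13 and 5 in the fifth with the shortest, with a median of 507 bases. Of the genes called lower in HDF, 21 lay in the fifth with the shortest and 1 in that with the longest. The median log2 fold change was -0.06 in the shortest and 0.09 in the longest in HUVEC, and -0.20 and 0.18 in HDF.

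Across 7828 genes with at least 10 CPM, the Spearman correlation of log2 fold change with coding length was 0.14 in HUVEC and 0.326 in HDF. With transcript length it was 0.154 and 0.282, with 3′ UTR length 0.098 and 0.128 over 7803 genes, and with GC content -0.268 and -0.317. Leaving out HUVEC whole cell replicate 1 brought the HUVEC values to 0.004 for transcript length, 0.012 for coding length, -0.001 for 3′ UTR length and -0.067 for GC content. Without HUVEC whole cell replicate 3 the value for coding length was 0.218, and without focal adhesion replicate 1 it was 0.06. In HDF it was 0.216 without whole cell replicate 2 or replicate 3 and 0.437 without replicate 1. Over all 12647 tested genes with a value, the correlation with coding length was lower, at 0.091 in HUVEC and 0.217 in HDF. Without single libraries these ran from -0.006 to 0.157 in HUVEC and from 0.139 to 0.304 in HDF.

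**Figure D4:**
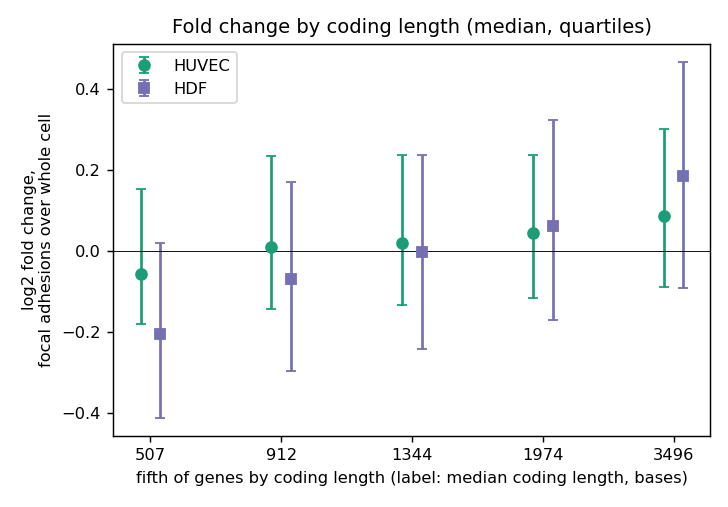
Median log2 fold change of focal adhesions over whole cells, with quartiles as bars, in 5 bins of genes by coding length, for HUVEC and HDF. In HDF the medians ran from -0.20 in the fifth with the shortest coding sequences to 0.18 in that with the longest, and in HUVEC from -0.06 to 0.09.

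HUVEC and HDF were compared within each preparation to ask how far focal adhesion RNA kept the cell type. In whole cells, PECAM1 (ENSG00000261371, chromosome 17, 64319415 to 64413776), an adhesion molecule of endothelial junctions, was at 458 ± 29.5 CPM (SD, n = 4) in HUVEC and 0.104 ± 0.127 CPM (SD, n = 3) in HDF. SOX17, an endothelial transcription factor, was at 29.9 ± 3.19 CPM in HUVEC and at 0 in every HDF whole cell library, at least 438-fold higher against the floor of 3 counts over the group, which is 0.0682 CPM. BST2, an antiviral membrane protein, was at least 761-fold higher, and the immune-type GTPase GIMAP1 at least 353-fold. In the other direction WNT5B, a secreted signaling protein, was at 164 ± 58.6 CPM in HDF and 0.0684 CPM in HUVEC, and TBX2, a transcription factor, at 149 ± 38.1 against 0.0645 CPM. THY1, a surface marker of fibroblasts, was at 199 ± 28.9 against 0.189 CPM, and FBLN1, a matrix protein, at 273 ± 97.6 against 0.186 CPM.

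More genes of this kind were found in whole cells. SPNS2, which exports sphingosine-1-phosphate, was at least 321-fold higher in HUVEC, NOVA2, a splicing regulator, at least 298-fold, and MIR3667HG, DIPK2B and WDFY4 at least 512-fold, 428-fold and 371-fold. RFLNA was at 182 ± 70.9 against 0.0664 CPM. The transcription factors SOX11 and FOXD1 were at least 589-fold and 485-fold higher in HDF against a HUVEC floor of 0.0495 CPM. KRT34, a keratin, was at 67.8 ± 13.1 CPM in HDF, MLPH at 66.2, IRS1, an adaptor of insulin signaling, at 39.3, and NPTX2 at 37.8 CPM.

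Isolated focal adhesions differed between cell types in the same kinds of gene. ERG was at 288 ± 27.1 CPM in HUVEC and 0.241 ± 0.0661 CPM in HDF (SD, n = 4 each), and TAL1, a transcription factor of blood and endothelium, was at least 792-fold higher in HUVEC against an HDF floor of 0.0516 CPM. COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632), the main fibrillar collagen chain, was at 1570 ± 133 CPM in HDF and 1.03 ± 0.378 CPM in HUVEC. TIMP3, an inhibitor of matrix proteases, was at least 936-fold higher in HDF against a HUVEC floor of 0.045 CPM, and SHOX2, a transcription factor, at least 694-fold.

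Other genes higher in HUVEC focal adhesions were the kinase BMX, at least 457-fold, the noncoding PCAT19, at least 537-fold, MYCT1 at 101 CPM, MGAT4A at 46.5, the Notch ligand JAG2 at 42.5 and MPZL2 at 24.4 CPM. Those higher in HDF included THY1 at 215 ± 32.5 against 0.0705 CPM, MXRA8, a matrix remodeling protein, at 249 ± 25.1 against 0.193 CPM, and WNT5B at 151 ± 10.3 against 0.0847 CPM. Levels in HDF were 68 CPM for HS3ST3A1, 56.5 for SPON2, 26.8 ± 8.19 for TFAP2C and 23.9 for the prostaglandin receptor PTGER2.

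Among lists, 22 of 23 endothelial markers were higher in HUVEC in both preparations, all but FLT1 (adjusted p with an estimated correlation 0.00443 in whole cells and 0.0066 in focal adhesions). Of 19 fibroblast markers, 17 were higher in HDF in both preparations (0.00215 and 0.00214), COL5A1 was higher in HUVEC by 0.58 and 0.64 on the log2 scale, and LOX did not pass. These were the lists that kept their call with an estimated correlation. Extracellular matrix genes had 10 higher and 27 lower in HUVEC whole cells (adjusted p = 0.000541 and 0.284 with an estimated correlation), and 10 and 26 in focal adhesions (2.12e-05 and 0.174). Ribosomal proteins had 15 higher and 7 lower in whole cells (0.0326 and, with an estimated correlation, 0.815) and 34 higher and 2 lower in focal adhesions (3.47e-05 and 0.428). Respiratory chain subunits had 16 and 2 in whole cells (0.0121 and 0.701) and 31 and 1 in focal adhesions (0.000349 and 0.447), and cell cycle genes 2 and 11 (0.0306 and 0.253) and 2 and 12 (0.00736 and 0.174). Protrusion-localized mRNAs passed in whole cells alone, with 1 higher and 7 lower (0.0116 and 0.186). Stress granule proteins, with 1 higher and 20 lower (0.000297 and 0.174), and actin genes, with 7 and 12 (0.0368 and 0.251), passed in focal adhesions alone.

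In all, 5439 genes differed between HUVEC and HDF whole cells (edgeR quasi-likelihood, Benjamini-Hochberg), 2554 higher and 2885 lower in HUVEC, and 5994 without HDF whole cell replicate 1. With DESeq2 size factors these were 2756 higher and 2625 lower. In focal adhesions 6390 genes differed, 3329 higher and 3061 lower. With scaling by library totals the median log2 fold change over all genes lay at -0.18 in focal adhesions, and the counts were then 2714 higher and 3864 lower. All 20 named genes of each comparison kept their call without any 1 library.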

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

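The tests on the HDF part of the length trend, on A-rich stretches in HDF whole cell replicate 1, on ribosomal proteins without that library, on other splits of the samples and on the cell types within those splits were chosen only after the result was seen.

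mRNAs with longer coding sequences had higher log2 fold changes in focal adhesions. In HDF the tables argue against priming inside transcripts at A-rich stretches as the whole cause. Among 4806 genes without such a stretch the Spearman correlation was 0.278. They also argue against GC content of the whole transcript as the whole cause, with a partial correlation of 0.336 given GC. GC content of the 3′ ends that were read was not tested. For both cell types together priming and GC content stay open. The lower values, 0.107 and 0.14, are those of HUVEC and go to 0.029 and 0.011 without HUVEC whole cell replicate 1. For the HDF part, retention of long mRNAs at adhesions may be a biological reading, which stays open and untested, since loss of short mRNAs during the isolation would give the same trend.

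HDF whole cell replicate 1 stood apart from replicates 2 and 3. Its departure had a partial Spearman correlation of 0.132 with the number of A-rich stretches given coding length, which priming at such stretches in this library could give. GC content and transcript length were not held fixed, and the 99 genes over 10-fold lower were not tested apart. The value therefore cannot decide for priming, which stays open. A focal adhesion preparation labelled as whole cell stays open, since the 113 genes higher in HUVEC focal adhesions stood above the other replicates by 18% of their HDF difference, between the bounds set for either answer. Reads shared between paralogs or pseudogenes stay open too, as 39.4% of the genes 10-fold lower had a count that was not whole in both other replicates, against 25.9% of all genes with at least 10 CPM. No biological explanation was tested, as the design names no difference between these replicates.

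Ribosomal protein mRNAs were lower in HDF focal adhesions. The tables argue against HDF whole cell replicate 1 as the cause, since the list median was -0.441 without it. On coding length and expression level alone, the median lay at percentile 0.01 of 10000 random lists matched on both. Members of those lists were drawn independently, while the ribosomal list had an estimated correlation of 0.297 between genes. The percentile therefore cannot decide on length and level alone. A lower content of these mRNAs at adhesions may be the reason, as a hypothesis only. The list's call ended with an estimated correlation (adjusted p = 0.215), though it passed by fry (0.0317), and other effects of the preparation were not tested.

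Other splits of the samples were counted for each comparison. In HUVEC focal adhesions 1 of 35 splits, the real one, gave as many as its 130 genes, and the highest other gave 7. In HDF it was again 1 of 35, with 198 genes and a highest other of 86. That other split grouped HDF whole cell replicate 1 with focal adhesion replicates 2 and 3. These had positive values on the second principal component (113.2, 8.4 and 6.1), and the other HDF libraries had negative ones. A structure of the samples across the preparations is therefore possible, and its cause was not tested. HUVEC against HDF gave 1 of 35 in whole cells, with 5439 genes and a highest other of 1397. In focal adhesions it gave 1 of 35, with 6390 and a highest other of 1. A share below 1 of 35 was not possible, so chance is less likely but not excluded. For HUVEC against HDF every other split mixed the cell types, so the lower counts there say little about chance. For the difference of effects the count says nothing about chance, since the real count was 0 (edgeR, 797 genes at an unadjusted p under 0.05, DESeq2 10, limma-voom 12) and 99 of 99 splits had to give as many. The highest other split gave 3941 genes, which points to a structure of the samples. The share of HUVEC libraries per group, combined as in the contrast, was largest in size at 1.417 to 1.5 in this split and the 2 others with at least 3483 genes, while splits with a smaller size gave at most 13.

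A sample far from the rest of its group was found in 9 of 146 groups of 4 libraries, where chance gives about 7.3. Ribosomal proteins took 11.9% of counts in HUVEC focal adhesion replicate 1 and 13.2 to 13.5% in the others. Fibroblast markers took 0.0189% in HUVEC whole cell replicate 2 and 0.02 to 0.0202% in the others. CACNG8 was at 80.4 CPM in HUVEC focal adhesion replicate 2, with 153 to 166 in the others, and FLNA at 1970 CPM there, with 2620 to 2720. TRAK2 was at 30.4 CPM in HUVEC whole cell replicate 4, with 18.5 to 19.1 in the others. MT-CO1 was at 2980 CPM in HUVEC focal adhesion replicate 4, with 2620 to 2660 in the others. G3BP1 was at 270 CPM in HUVEC whole cell replicate 2, with 303 to 306 in the others. PXN was at 246 CPM in HUVEC focal adhesion replicate 1, with 291 to 294 in the others. TFAP2C was at 39 CPM in HDF focal adhesion replicate 2, with 21.6 to 23.7 in the others.

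The focal adhesion effect of 8 lists differed between cell types by camera with the preset correlation, and of 0 with an estimated correlation or by fry. Medians of the difference, HUVEC less HDF, were 0.278 for mitochondrially encoded mRNAs (adjusted p = 0.446 with an estimated correlation), 0.225 for ribosomal proteins (0.524) and 0.275 for protrusion-localized mRNAs (0.182). Lists with a lower effect in HUVEC were stress granule proteins at -0.274 (0.164), heat shock at -0.118 (0.167), immediate early genes at -0.109 (0.446), extracellular matrix at -0.083 (0.446) and focal adhesion proteins at -0.016 (0.164).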

How the results depend on the processing

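Leaving out HDF whole cell replicate 1 for lists, overlap and correlation, leaving out libraries for transcript properties and shares, and the 10 CPM limit for properties were chosen only after the data were seen. Of the named genes' values, 106 kept direction and side of the threshold with DESeq2 size factors, 106 with library totals and 86 with the replicate block, where 21 lost their call and 1 changed sign. The calls lost with the block were 4 in HUVEC (CACNG8, DST, MIRLET7A1HG and MAP1B) and 17 in HDF, including 10 named genes that fell there, G3BP1 and SEC62 (adjusted p from 0.0798 to 0.354). Without single libraries 737 were the same, 60 lost their call, 1 gained one and 6 changed sign. HUVEC focal adhesion calls, 130 as reported, numbered 305 with DESeq2, 738 with limma-voom and sample weights, 313 without an expression filter and 270 with these groups alone in the fit, of which 128, 127, 112 and 124 were among the 130. They numbered 84 without the libraries with contradicting labels and 78 to 108 without single libraries. HDF calls, 198 as reported, numbered 729, 1337 and 438 with DESeq2, limma-voom and no filter, 327 with the 5 CPM filter, 62 with these groups alone (62 higher and 0 lower in edgeR, 1584 unadjusted), 119 at an absolute log2 fold change of at least 1, 95 without the libraries with contradicting labels and 92 to 598 without single libraries. With the groups of the characteristics, which put libraries of both cell types into 1 group, edgeR called 0 genes in HUVEC (437 at an unadjusted p under 0.05), 0 in HDF (1358 unadjusted) and 887 between focal adhesions of HUVEC and HDF. Of the 6390 reported there, 4224 had an absolute log2 fold change of at least 1. The difference of effects had 10 genes with DESeq2, 12 with limma-voom, 42 without a filter and 0 to 1 without single libraries. With the replicate number as a block (replicate block), 63 genes were called in HUVEC, 45 in HDF (43 higher and 2 lower), 0 for the difference (479 unadjusted, edgeR), 4631 between whole cells and 5804 between focal adhesions. Residual correlations between preparations of equal number were -0.122 to 0.106 in HUVEC and -0.161 to -0.13 in HDF. They gave no sign of pairing but cannot exclude it, since residuals were taken from means of 3 or 4 libraries. Lists past the test with an estimated correlation numbered 5 in HUVEC, 2 in HDF and 0 for the difference. By fry they numbered 8, 9 and 0. In HDF, fry passed lists that failed with an estimated correlation. These included very long mRNAs (fry adjusted p = 0.00373), heat shock (0.0065), stress granule proteins (0.0113), snoRNA hosts (0.0113), the ER machinery (0.0132) and ribosomal proteins (0.0317). Mitochondrially encoded mRNAs (0.222), extracellular matrix (0.222), actin genes (0.13) and respiratory chain subunits (0.125) passed neither. The correlation of effects, 0.223 over all genes, was 0.138 without HDF whole cell replicate 1, and at 10 CPM or more it was 0.499 with that library and 0.428 without it. ACTB in HUVEC, 0.04 as reported, turned to -0.041 with library totals, and ran from -0.04 to 0.162 without single libraries, negative without whole cell replicate 2 or 3 or focal adhesion replicate 3. PXN in HDF ran from -0.388 to 0.412, negative without whole cell replicate 1 or focal adhesion replicate 4. MALAT1 in HDF turned to 0.056 with the block and ran from -0.634 to 0.587, positive without whole cell replicate 1. Without single libraries, correlations in HUVEC ranged from 0.004 to 0.246 for transcript length, -0.001 to 0.159 for 3′ UTR length and -0.37 to -0.067 for GC. In HDF these ranged from 0.188 to 0.36, 0.085 to 0.15 and -0.333 to -0.235. Besides settings that test fewer genes or libraries by their construction, the cause was not tested. Thinning to the smallest library kept 123 of 130 and 183 of 198 calls, and what greater depth would add was not tested. At this depth and number of libraries, 3.33% of genes changed 1.5-fold were recovered in HUVEC on simulated data.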

Other observations

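The matched-list tests of protrusion-localized mRNAs and focal adhesion proteins were fixed before their result was seen, percentiles of other lists are given as values without a prediction, and the genes below were chosen after their values were seen.

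Other genes rose in focal adhesions of both cell types. DIAPH1, a formin that elongates actin filaments, had log2 fold changes of 2.26 in HUVEC and 1.94 in HDF, and the scaffold IQGAP1 2.12 and 2.02. SPTBN1, a spectrin, had 2.02 and 1.78, ANLN, which bundles actin in the cleavage furrow, 1.99 and 1.75, and SVIL, a membrane-bound actin regulator, 1.78 and 1.27. LMO7 had 2.29 and 1.58, AMOT, a binder of YAP at junctions, 1.49 and 1.49, and TLN2, the second talin, 1.72 and 1.70. LPAR1, a receptor for lysophosphatidic acid, had 1.95 and 1.71, and the potassium channel KCNK6 2.38 and 1.89. These are examples without an enrichment test, and the actin and contractile list had 0 of 36 genes higher in HUVEC and 1 in HDF.

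Of the ER list 1 gene, SEC62, was called in each cell type (1.08 and 1.07). TMED2, a cargo receptor of the secretory pathway, had log2 fold changes of 0.95 in HUVEC and 0.74 in HDF, and REEP3, which keeps ER off chromosomes, 0.66 and 0.87. The mitochondrial tRNA genes MT-TP (1.90 and 1.62), MT-TV (1.47 and 1.26) and MT-TL1 (1.18 and 1.02) were higher in both. The ER list lay at percentile 100 of random lists matched on coding length and level in both cell types, its medians of 0.38 and 0.24 standing above the random lists' upper bounds of 0.133 and 0.096. The HDF median was 0.12 without HDF whole cell replicate 1, and the HDF list did not pass with an estimated correlation (adjusted p = 0.0782, and 0.227 without that library).

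A hypothesis was that coding length and expression level alone could raise protrusion-localized mRNAs and mRNAs of focal adhesion proteins. Against it for the protrusion list, its median lay at percentile 100 of 10000 matched random lists in both cell types. For focal adhesion proteins the median lay at percentile 96.4 in HUVEC and 83.87 in HDF, so length and level alone could give that median. A median cannot show a rise in part of a list. Of its 63 members, 6 were called higher in HUVEC and 10 in HDF. In the fifth with the longest coding sequences, 53 and 84 of 1566 genes were called higher. Whether length and level alone could give the members' calls was not tested. Very long mRNAs lay at percentiles 96.51 and 98.06, stress granule proteins at 6.45 and 98.7, and respiratory chain subunits at 0.63 and 47.72. Ribosomal proteins lay at 11.34 in HUVEC.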
